A study of Mus musculus with 26 samples.

How the data were processed

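RNA was measured in pancreatic islets of C57BL/6J mice, hand-picked and pooled by sample, from neonates at postnatal day 5, whose islets the sample titles call small or large, and from adults at 2.5 months. The labels describe total RNA, removal of ribosomal RNA during library preparation, and 3 batches. Library names of 20 neonatal and 6 adult libraries were matched to groups and batches from the labels before the data were examined, and so were the comparisons and their tests, the gene lists, the rule for naming genes and most alternatives. Some tests of explanations were chosen later.

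The deposited table holds 13641 genes and 26 libraries. The authors gave 1 FPKM value (fragments per kilobase of gene and per M, mega, of fragments) for each gene and library. The processing notes of the authors name the mm10 genome, STAR 2.6a, HTSeq 0.11.1 and edgeR, with no role given for each. Beside these values, the authors deposited a log2 fold change and a mean log2 count per M for their comparison of all neonatal with all adult libraries. The authors also deposited a score for each gene, the F statistic of that comparison, with its p-value and FDR, and an UP or DOWN mark. Recomputed on the file, the deposited FDR was the Benjamini-Hochberg value of the p-value. The authors marked 1728 genes UP and 789 DOWN. Their log2 fold changes lay below those computed here by 0.228 at the median (median difference -0.228), and the scaling behind them is not stated. Of the UP genes 1720 were also called higher here, and of the DOWN genes 718 lower. The deposited gene lengths, the annotation and any filter on genes are not stated either. Spreadsheet software had turned 20 gene names into dates, and these were kept in the fits but not named.

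Fragment counts were recovered from the FPKM, because each value times the gene's length and the library total must be a whole number. A common length per gene and a total per library were found such that 100.0% of values came out whole within 0.03 fragments. Rebuilt FPKM differed from the deposited ones by at most 1.73e-03 of their size. The recovered totals ran from 15.5 M to 32.0 M fragments, over the listed genes only. On simulated data the recovery returned 96.1% of 354666 counts exactly. The median recovered length was 3293 bases, and 0.2% of lengths equalled the summed exons of GENCODE M21, which leaves the authors' annotation and their definition of gene length open. These counts served only for depth and for an alternative fit. Gene positions are those of GENCODE M21, in which 13387 of 13641 names were found.

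Genes with an FPKM of at least 1 in at least 6 libraries, the size of the smallest group, were kept (13402 genes). Their values were log2 transformed after adding 1 and fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, using a term for each group and each batch. Spread was moderated with a trend on the mean level and robustly (eBayes). The contrasts were the mean of small and large neonatal islets against adult islets, small against large, and each size against adult. A further fit on batches 2 and 3 tested whether the neonatal against adult difference differed between them. Benjamini-Hochberg adjusted p under 0.05 over all genes kept was called, and limma's test was used on both sides throughout. For a gene, a difference within a batch is that of mean log2 values. For a list, it comes from the fit to that batch. The standard error is the moderated one of limma.

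The 35 gene lists, drawn up from general knowledge, cover β cell identity and maturity, α cells, δ, PP and ε cells, fetal and oncofetal genes, β cell disallowed genes, hormone granules and exocytosis, and islet autoantigens. Others cover DNA replication and S phase, mitosis, cyclin-dependent kinase inhibitors and G1 regulators, replication-dependent histones, damage checkpoint signalling, homologous recombination and Fanconi, non-homologous end joining, base excision, nucleotide excision and mismatch repair. Further lists are p53 targets, senescence, pro-apoptotic, anti-apoptotic, antioxidant, unfolded protein response, interferon response and MHC class I, respiratory chain of the nucleus and of the mitochondrion, and immediate early and heat shock genes. Cell type lists hold acinar, duct, endothelial, mesenchymal, macrophage, lymphocyte, erythroid and Schwann cell genes. The 32 lists with at least 5 genes kept were tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Each gene of these cell type lists that was kept stood in no other cell type list. The erythroid and lymphocyte lists, below 5 genes, are given gene by gene, and the mitochondrially encoded list had no gene to test. Members were also adjusted over the list alone.

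Named genes follow a rule. Part 1 is a fixed set of islet hormone, β cell, proliferation and damage response genes. Part 2 is the 6 largest rises and 6 largest falls among called genes with the same direction in every batch that held both groups and a mean of at least 5 FPKM in the higher group, leaving out predicted genes and small RNAs. Part 3 is up to 2 called members of each list in either direction with a mean of at least 1 FPKM in the higher group. Genes outside the rule are said to be chosen after their values were seen. Cdkn2a, which the rule names, is not analysed here. Some other genes that the rule names are not reported here.

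Hormone shares were tested by exact permutation of labels within batches, on both sides, over all arrangements, in place of the 100000 resamples first planned, since some groups held fewer than 10 libraries. Chosen after the data were seen, mesenchymal medians between small and large islets, also with acinar and duct levels as covariates, were tested on both sides over all 24500 arrangements within batches, and over 350 in batches 2 and 3. The signs of genes called in batch 1 were tested on the upper side over the same 350. Calls were also counted over all 64 distinct exchanges within 7 pairs of small and large libraries with equal library-name numbers. Correlations across libraries used levels centred within batches and 1e+05 permutations.

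The gene tests were tested on simulated data drawn around the fitted means with each gene's own spread and no group difference, after changes of 0.5 or 1 on the log2 scale were added to 200 genes. They found 78% and 99% of these changes between neonatal and adult, with 2.75% false calls, and 82% and 97% between small and large, with 2.19% false. In the 18 libraries without batch 1 they found 72% and 93%, with 7.3% false. Of 50 simulated lists of 20 genes that were shifted, camera called 100% with the preset and with an estimated correlation, and fry called 100%. Unshifted lists were called in 4%, 2% and 2%. Simulated lists take genes at random, so they lack the correlation between genes of 1 program.

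The alternatives were pseudocounts of 0.1 and 5, no filter and an FPKM minimum of 5, median-of-ratios rescaling, quantile normalization, rescaling without hormone genes, no batch term, single batches, leaving out batch 1, plain eBayes, array weights, a minimum absolute log2 change of 1, each adult left out, and blocks by sample number. Lists were also tested with camera at an estimated correlation and with fry. Chosen after seeing the data were limma-voom on recovered counts, fits without the adults of batch 2 or of batch 3 or without neonatal large replicate 14, batch 1 alone, and single batches, quantile normalization and each adult left out for the lists and for the difference between batches, and hormone shares in pairs of small and large libraries with equal library-name numbers, by exact sign flips. Random splits of the libraries within batches, 100 with the real one included, were fitted the same way. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 made the shares, the recovery and the plots.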

Results

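Gene expression was measured by RNA sequencing in hand-picked pancreatic islets of C57BL/6J mice at 2 ages. Islets of neonatal mice at postnatal day 5 had been separated by size into small and large, and adult islets came from mice aged 2.5 months. The libraries numbered 9 for neonatal small, 11 for neonatal large and 6 for adult islets. They were made in 3 batches: batch 1 held 4 small and 4 large libraries, batch 2 held 3 small, 4 large and 4 adult ones, and batch 3 held 2 small, 3 large and 2 adult ones. Nothing in the labels says whether libraries came from separate animals, so every p-value measures the spread between libraries. The fragment totals recovered from the FPKM ran from 15.5 M to 32.0 M (mega) per library. In batch 1, the small islet libraries had 15.5 M to 18.3 M and the large ones 21 M to 23.2 M. The adult libraries had 25.2 M to 27.4 M in batch 2 and 17.3 M and 18.5 M in batch 3. The series is titled as a study of how α and β cells respond to DNA damage during development, so genes of cell identity, proliferation, damage signalling and DNA repair are described group by group. All log2 changes are of FPKM + 1, a scale that understates changes of genes near or below 1 FPKM. Values in brackets after a gene are its log2 change over all batches and then within the batches named.

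The comparison of neonatal with adult islets asks which transcripts separate islets of newborn mice from mature ones. Neonatal islets had far more transcripts of cell division, fetal, blood vessel and connective tissue genes. Adult islets had more of the unfolded protein response, more so in batch 2. None of these lists passed with an estimated correlation (adjusted p 0.205 to 0.392). Adult islets had a larger share of insulin transcripts. H19, an imprinted fetal noncoding RNA, averaged 113 ± 62.1 FPKM in neonatal islets (SD, n = 20) and 0.00696 ± 0.0111 in adult ones (n = 6). It changed by 6.30 ± 0.24 (SE, adjusted p = 7.49e-17) on the log2 scale, with 6.00 in batch 2 and 7.01 in batch 3. Eln, which encodes elastin, averaged 175 ± 299.5 FPKM in neonatal islets (SD, n = 20) and 1.92 ± 1.18 in adult ones (n = 6). Eln changed by 5.09 ± 0.62 (SE, adjusted p = 1.96e-07), with 5.20 in batch 2 and 5.01 in batch 3. The other 4 of the 6 largest rises were the histone genes Hist1h3c (4.79), Hist1h3b (4.38), Hist1h2ab (4.36) and Hist1h2af (4.31), copies of near-identical sequence whose reads are assigned with some uncertainty. Pdyn, which encodes the opioid precursor prodynorphin, showed the largest fall, from 53.2 ± 26.1 FPKM in adult islets to 0.621 ± 0.615 in neonatal ones. Pdyn changed by -5.04 ± 0.25 (SE, adjusted p = 5.59e-15), with -5.10 in batch 2 and -4.92 in batch 3. Among the other 5 largest falls were the antigen presentation genes H2-Aa (-3.67, batches -3.64 and -3.56), H2-Eb1 (-3.58, batches -3.59 and -3.43) and Cd74 (-3.49, batches -3.45 and -3.42). The stress genes Mt2 (-3.76, batches -5.43 and -0.83), a metallothionein, and Chac1 (-3.49, batches -4.70 and -1.5), a target of the unfolded protein response, made up the rest.

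Of 13402 genes tested with limma, 9096 differed between neonatal and adult islets, 6272 higher and 2824 lower in neonatal islets. An absolute log2 change of at least 1 was reached by 1340 of the higher and 231 of the lower genes, by 1090 and 398 after median-of-ratios rescaling and by 795 and 409 after quantile normalization. In batches 2 and 3, which held both ages, 8246 of the 9096 genes (90.7%) kept direction. These batches gave the calls, so this is partly built in. The balance of directions rested on the scaling: the median log2 change of all genes was 0.16 as deposited, -0.018 after median-of-ratios rescaling and -0.061 after quantile normalization. Those scalings gave 4476 higher and 4663 lower genes, and 4026 and 5021, so the majority turned to lower. Each list below is therefore given as the median log2 change of its genes minus that of all genes. In the submitters' own table, 9207 genes had an FDR under 0.05, with 4192 positive and 5015 negative log2 fold changes. Of the 9096 genes, 6928 passed in both with the same sign and 7 with opposite signs.

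The gene lists were fixed before the data were examined and are tested against all other genes. In neonatal islets, 9 of 32 lists lay above and 6 below the other genes at an adjusted p under 0.05, with a preset correlation between genes. None of the 15 passed when that correlation was estimated from the data (camera in limma), so the p with an estimated correlation is given with each. Splits of the libraries drawn at random within batches called 12 lists at the median and up to 20. The counts of members that follow are adjusted over all genes. Adjusted over the list alone they were the same except where given. The test pointed lower while the median relative to all genes was above 0 for the senescence and acinar lists, neither of which was called. The positions of some genes central to these lists on the mouse genome (mm10) are chromosome 7, 135689784 to 135716361 for Mki67, chromosome 11, 101488764 to 101551955 for Brca1, chromosome 9, 53439149 to 53536740 for Atm and chromosome 17, 29090976 to 29100727 for Cdkn1a.

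**Figure D1:**
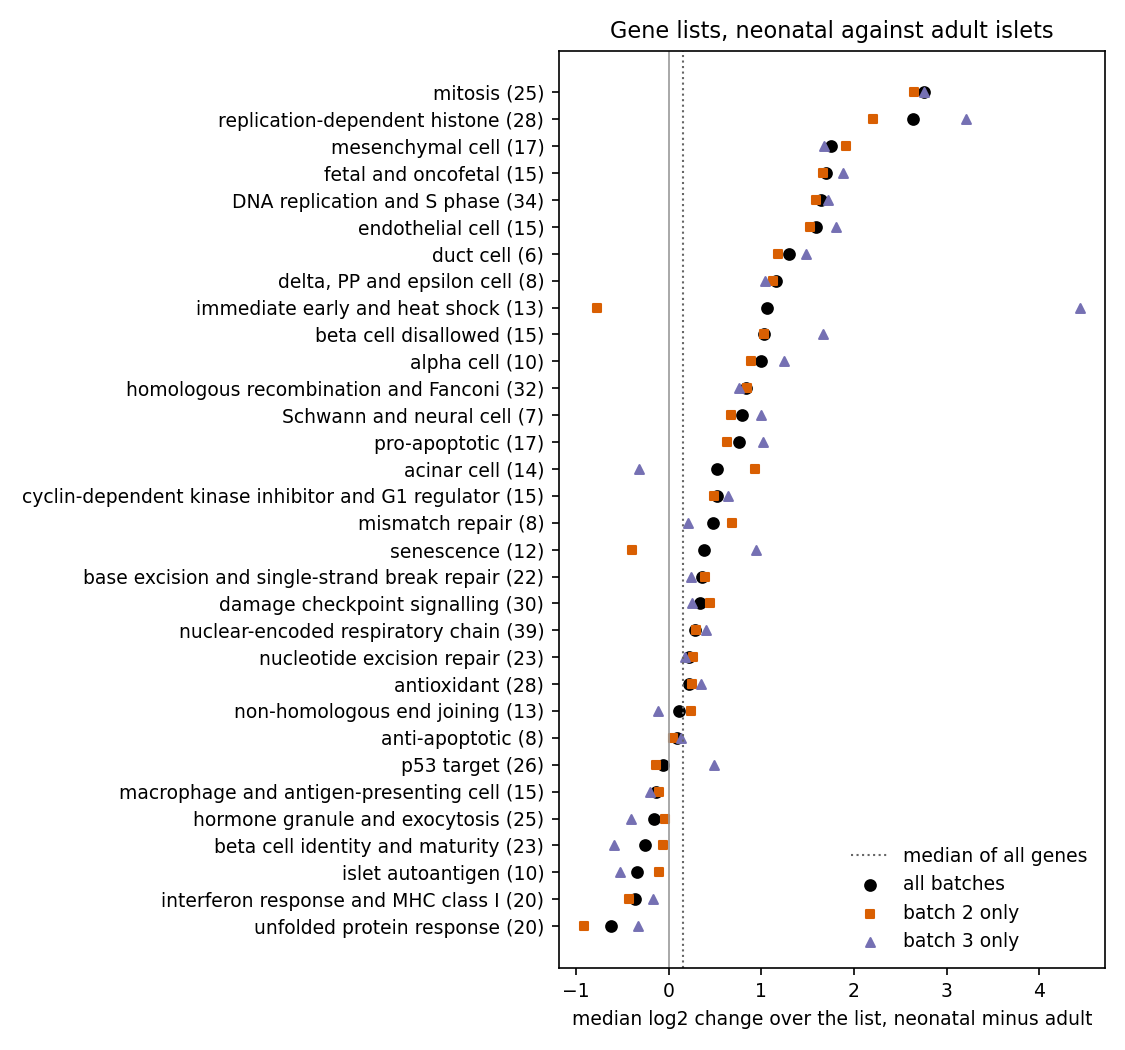
Median log2 change (horizontal axis, neonatal minus adult) of each gene list with at least 5 genes, as black circles over all batches, orange squares in batch 2 and purple triangles in batch 3. The number of genes is in brackets, the dotted line marks the median of all genes, and mitosis lies highest at 2.76 over all batches.

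Mature β cell genes were split between the ages. Ins2, an insulin gene, averaged 58390 ± 7705 FPKM in neonatal islets (SD, n = 20) and 93130 ± 12460 in adult ones (n = 6). Ins2 changed by -0.62 ± 0.12 (SE, adjusted p = 3.68e-05), with -0.64 in batch 2 and -0.59 in batch 3. Ins1, the other insulin gene, averaged 46580 ± 4294 FPKM in neonatal islets (SD, n = 20) and 48090 ± 7595 in adult ones (n = 6). Ins1 did not pass, at 0.011 ± 0.11 (SE, adjusted p = 0.934), with 0.022 in batch 2 and -0.0045 in batch 3. Reads shared between these paralogs leave the division between them uncertain. Ucn3, a marker of β cell maturity, fell to 119 ± 22.7 FPKM in neonatal islets from 289 ± 41.6 in adult ones. Ucn3 changed by -1.24 ± 0.12 (SE, adjusted p = 2.17e-09), with -1.0 in batch 2 and -1.64 in batch 3. Of the 23 genes of β cell identity and maturity, 11 fell, among them Cox6a2 (-2.95, batches -2.76 and -3.30) and the prolactin receptor gene Prlr (-1.90, batches -1.21 and -3.14). Another 3 rose, the transcription factor genes Pdx1 (0.64, batches 0.77 and 0.38), Nkx2-2 (0.55, batches 0.59 and 0.45) and Nkx6-1 (0.20, batches 0.16 and 0.20). Nkx6-1 was chosen after its values were seen and was at -0.0056 after median-of-ratios rescaling. Adjusted over the list alone, 2 rose and 10 fell. Mafa, a transcription factor of mature β cells, had 145 ± 38.8 FPKM in neonatal and 129.5 ± 15 in adult islets. Mafa did not pass, at -0.047 ± 0.12 (SE, adjusted p = 0.755), with -0.15 in batch 2 and 0.067 in batch 3. The list median was -0.42 (-0.26 in batch 2 and -0.74 in batch 3, adjusted p = 0.00206, or 0.375 with an estimated correlation). It was -0.14 and not called after quantile normalization (adjusted p = 0.108). Mesenchymal and endothelial markers rose, so the fall is not assigned to β cells. Insulin transcripts made up 24.7% ± 2.44 (SD) of all FPKM in the 12 neonatal libraries of batches 2 and 3 and 31.1% ± 3.35 in the 6 adult ones. The difference of -6.36 points passed in an exact permutation test within batches, on both sides (p = 0.000722 over 6930 arrangements, adjusted p = 0.00289 over 4 tests). It was -5.37 points in batch 2 (exact p = 0.0152) and -8.31 in batch 3 (exact p = 0.0476, the smallest that 21 arrangements can give).

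Genes that mature β cells keep low were higher in neonatal islets. Of 15 such "disallowed" genes 14 rose, among them Igfbp4 (2.56, batches 2.69 and 2.49) and Mgst1 (2.21, batches 2.17 and 2.46). The list median was 0.87 (0.84 in batch 2 and 1.51 in batch 3, adjusted p = 0.000794, or 0.375 with an estimated correlation). Mesenchymal and endothelial markers rose too (medians 1.59 and 1.43), so the rise is not assigned to β cells. The fetal and oncofetal list behaved alike, with 14 of 15 genes higher, among them H19 and Dlk1 (4.30, batches 3.87 and 5.11). The fetal median was 1.54 (1.48 in batch 2 and 1.73 in batch 3, adjusted p = 9.71e-06, or 0.205 with an estimated correlation). Of 25 hormone granule and exocytosis genes, 3 rose and 11 fell. The granule proteins Scg2 (-0.62, batches -0.41 and -0.99) and Scg5 (-0.58, batches -0.50 and -0.69) fell. In contrast, Chgb (0.64, batches 0.80 and 0.33) and the membrane fusion gene Stx1a (1.18, batches 1.10 and 1.29) rose, as did Rph3al (0.25, batches 0.22 and 0.25), which was chosen after its values were seen. The median was -0.32 (-0.23 in batch 2 and -0.56 in batch 3, adjusted p = 0.0108, or 0.459 with an estimated correlation). Of 10 islet autoantigen genes, 6 fell, with Gad1 (-1.39, batches -1.06 and -2.01) the largest fall, and 1 rose, Ica1 (0.17, batches 0.19 and 0.10), which was at -0.034 after median-of-ratios rescaling. The autoantigen median was -0.50 (-0.29 in batch 2 and -0.68 in batch 3, adjusted p = 0.0108, or 0.375 with an estimated correlation). Under quantile normalization neither the granule list (adjusted p = 0.267) nor the autoantigen list (0.281) was called.

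The other endocrine cell types showed mixed changes. Gcg, the glucagon gene of α cells, averaged 14650 ± 5078 FPKM in neonatal islets (SD, n = 20) and 23560 ± 5338 in adult ones (n = 6). Gcg changed by -0.47 ± 0.20 (SE, adjusted p = 0.0379), with -0.44 in batch 2 and -0.43 in batch 3. Its share of hormone FPKM was 13.0% ± 2.18 in the 12 neonatal libraries of batches 2 and 3 and 14.0% ± 4.25 in the 6 adult ones, which did not pass, with exact permutation p = 0.531. Sst had 2769 ± 599 FPKM in neonatal and 3100 ± 563 in adult islets (adjusted p = 0.388, -0.22 in batch 2 and 0.019 in batch 3). Ppy had 3044 ± 1292 and 3924 ± 827 (adjusted p = 0.58, -0.33 in batch 2 and 0.14 in batch 3). Of 10 α cell genes 6 rose, led by the amino acid transporter gene Slc38a5 (3.50, batches 3.62 and 3.35). The 3 that fell were Gcg, Gc (-1.54, batches -1.28 and -1.92) and Ttr (-0.63, batches -0.62 and -0.56). The median of the α cell list was 0.85 (0.69 in batch 2 and 1.09 in batch 3, adjusted p = 0.342) and was not called. Ghrl, the ghrelin gene of ε cells, averaged 203 ± 85 FPKM in neonatal islets (SD, n = 20) and 11.3 ± 4.18 in adult ones (n = 6). Ghrl changed by 4.12 ± 0.22 (SE, adjusted p = 2.7e-14), with 3.65 in batch 2 and 4.90 in batch 3. It was among the 6 of 8 δ, PP and ε cell genes that rose. Their median was 1.0 (0.92 in batch 2 and 0.89 in batch 3, adjusted p = 0.0503).

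**Figure D2:**
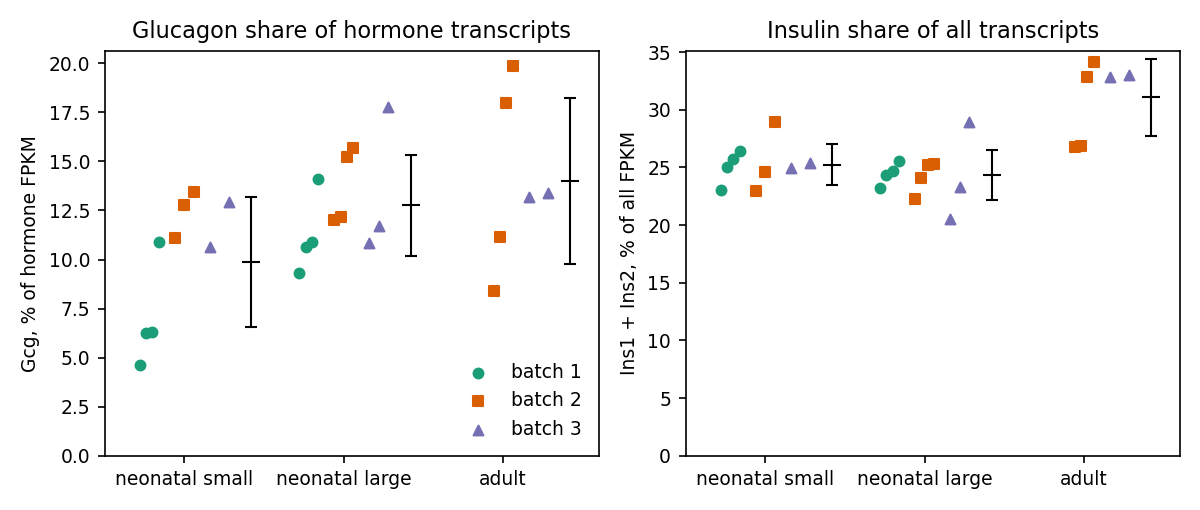
Gcg FPKM as a percent of the FPKM of Ins1, Ins2, Gcg, Sst and Ppy (left) and Ins1 plus Ins2 as a percent of all FPKM (right), per library, by group and batch. Black marks give the mean and SD of each group, and the insulin share averaged 31.1% in the 6 adult libraries.

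Over all batches, the mitosis list had the highest median of the tested lists. Mki67, a marker of dividing cells, averaged 40.6 ± 6.41 FPKM in neonatal islets (SD, n = 20) and 2.13 ± 0.536 in adult ones (n = 6). Mki67 changed by 3.65 ± 0.11 (SE, adjusted p = 6.61e-20), with 3.66 in batch 2 and 3.63 in batch 3. All 25 mitosis genes rose, led by Top2a (3.72, batches 3.75 and 3.70). The mitosis median was 2.6 (2.46 in batch 2 and 2.61 in batch 3, adjusted p = 6.63e-18). All 34 genes of DNA replication and S phase rose as well, led by Uhrf1 (3.06, batches 2.96 and 3.25) and Mcm3 (2.70, batches 2.66 and 2.81). The S phase median was 1.49 (1.39 in batch 2 and 1.57 in batch 3, adjusted p = 8.3e-16). Of 28 replication-dependent histone genes 26 rose, with a median of 2.49 (2.02 in batch 2 and 3.06 in batch 3, adjusted p = 6.11e-11). With an estimated correlation adjusted p = 0.212 for mitosis, 0.205 for S phase and 0.279 for histones. Among 15 cyclin-dependent kinase inhibitors and G1 regulators, 9 rose and 2 fell. The cell cycle inhibitors Cdkn1c (2.45, batches 2.05 and 3.29) and Cdkn2c (1.87, batches 1.86 and 1.90) rose, and the inhibitor Cdkn2b (-1.30, batches -1.74 and -0.48) and the cyclin Ccnd2 (-0.31, batches -0.069 and -0.74) fell. That list was not called (0.36 (0.30 in batch 2 and 0.49 in batch 3, adjusted p = 0.0835)).

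Most homologous recombination genes rose, and damage checkpoint genes in part. Brca1, a gene of homologous recombination, averaged 3.61 ± 0.52 FPKM in neonatal islets (SD, n = 20) and 0.811 ± 0.192 in adult ones (n = 6). Brca1 changed by 1.31 ± 0.078 (SE, adjusted p = 7.45e-14), with 1.21 in batch 2 and 1.48 in batch 3. Of 32 homologous recombination and Fanconi genes, 28 rose, among them Ube2t (1.87, batches 1.74 and 2.15), and only Rad52 (-0.52, batches -0.59 and -0.36) fell. Their median was 0.68 (0.65 in batch 2 and 0.60 in batch 3, adjusted p = 4.62e-06), with adjusted p = 0.212 with an estimated correlation. Of 30 damage checkpoint genes 18 rose, among them the histone gene H2afx (2.17, batches 1.85 and 2.78), Clspn (2.02, batches 2.03 and 2.01) and the checkpoint kinase gene Chek1 (0.82, batches 0.58 and 1.20). Trp53, the p53 gene, also rose, from 16 ± 3.11 to 23.5 ± 2.68 FPKM (0.50 ± 0.10 (SE, adjusted p = 5.41e-05), 0.23 in batch 2 and 1.01 in batch 3). Mdm2, the p53 inhibitor gene and the sole checkpoint gene that fell, changed by -0.14 ± 0.056 (SE, adjusted p = 0.0263), with -0.29 in batch 2 and 0.10 in batch 3. Atm, the kinase gene of the response to double-strand breaks, did not pass the test over all batches (-0.13 ± 0.18 (SE, adjusted p = 0.514)). It took opposite directions within them (0.39 in batch 2 and -1.06 in batch 3, adjusted p of the difference = 6.83e-05). The checkpoint list was not called (0.18 (0.25 in batch 2 and 0.10 in batch 3, adjusted p = 0.0503)).

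No other repair list was called. Of 8 mismatch repair genes 6 rose, led by Exo1 (1.58, batches 1.64 and 1.5), with a median of 0.33 (0.49 in batch 2 and 0.053 in batch 3, adjusted p = 0.0503). Of 22 base excision and single-strand break repair genes 13 rose, among them Neil3 (1.97, batches 1.97 and 1.97), Ung (1.17, batches 0.90 and 1.66) and Parp1 (0.42 ± 0.065 (SE, adjusted p = 2.77e-06), 0.56 in batch 2 and 0.17 in batch 3). The 3 that fell were Apex2 (-0.32, batches -0.34 and -0.31), Neil2 (-0.26, batches -0.05 and -0.61) and Aptx (-0.11, batches -0.092 and -0.13), and the median was 0.20 (0.20 in batch 2 and 0.083 in batch 3, adjusted p = 0.185). Of 23 nucleotide excision repair genes 13 rose, led by the replication protein A genes Rpa2 (1.53, batches 1.44 and 1.74) and Rpa3 (1.08, batches 1.40 and 0.63), while Ercc6 (-0.40, batches -0.47 and -0.30) fell. Its median was 0.067 (0.072 in batch 2 and 0.019 in batch 3, adjusted p = 0.268). Of 13 non-homologous end joining genes 4 rose, Mad2l2 (0.57, batches 0.47 and 0.74), Aplf (0.45, batches 0.55 and 0.29), Xrcc4 (0.28, batches 0.38 and 0.12) and Poll (0.17, batches 0.19 and 0.10). The 2 that fell were Xrcc5 and Dclre1c, and the median was -0.048 (0.045 in batch 2 and -0.27 in batch 3, adjusted p = 0.806). Xrcc5, which encodes the Ku80 end-binding protein, changed by -0.29 ± 0.087 (SE, adjusted p = 0.00455), with -0.022 in batch 2 and -0.76 in batch 3. Dclre1c changed by -0.21 ± 0.08 (SE, adjusted p = 0.0267), with -0.20 in batch 2 and -0.23 in batch 3. Aptx, Xrcc4 and Poll were chosen after their values were seen, and Poll was at -0.0036 after median-of-ratios rescaling. After median-of-ratios rescaling the members that rose and fell were 8 and 3 for nucleotide excision repair, 12 and 4 for base excision repair, and 2 and 4 for end joining, whose majority thus turned to lower. For homologous recombination they were 24 and 3.

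Most pro-apoptotic genes were higher in neonatal islets. Of 17 pro-apoptotic genes 15 rose and none fell, among them Bik (1.24, batches 1.24 and 1.21). The pro-apoptotic median was 0.60 (0.43 in batch 2 and 0.86 in batch 3, adjusted p = 0.000794), with adjusted p = 0.212 with an estimated correlation. Of 8 anti-apoptotic genes 3 rose, Bcl2 (0.78, batches 0.81 and 0.79), Xiap (0.63, batches 0.98 and 0.047) and Mcl1 (0.44, batches -0.052 and 1.32), which was chosen after its values were seen. The 2 that fell were Birc2 (-0.29, -0.24 in batch 2 and -0.37 in batch 3) and Birc3. Birc3 changed by -1.72 ± 0.36 (SE, adjusted p = 0.000182) over all batches but took opposite directions within them (-2.88 in batch 2 and 0.28 in batch 3). The anti-apoptotic median was -0.072 (-0.15 in batch 2 and -0.02 in batch 3, adjusted p = 0.756), and turned to 0.029 after quantile normalization.

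Targets of p53 and acute stress genes depended on the adult batch. Cdkn1a, the p21 gene, averaged 19.4 ± 5.51 FPKM in neonatal islets (SD, n = 20), 47.6 in the 4 adult libraries of batch 2 and 5.41 in the 2 of batch 3. Its change was therefore -1.58 in batch 2 and 1.76 in batch 3, opposite directions that differed with adjusted p = 7.31e-08, and over all batches it was -0.37 ± 0.37 (SE, adjusted p = 0.394). Of 26 p53 target genes, 7 rose, among them Plk2 (2.10, batches 1.36 and 3.42) and Btg2 (0.95, batches 0.28 and 2.09). Another 8 fell, among them Trp53inp1 (-1.58, batches -1.92 and -0.94) and Plk3 (-1.57, batches -2.55 and 0.051). Adjusted over the list alone, 7 rose and 7 fell. The p53 target median was -0.22 (-0.33 in batch 2 and 0.34 in batch 3, adjusted p = 0.111). Among 13 immediate early and heat shock genes, the early response genes Fos (2.34, batches 0.78 and 5.09) and Egr1 (2.08, batches 0.61 and 4.63) rose. Hspa1a and Hspa1b, near-identical heat shock genes, fell over all batches (-2.75 and -2.99) but changed by -5.37 in batch 2 and 1.84 in batch 3 for Hspa1a and by -5.84 in batch 2 and 1.99 in batch 3 for Hspa1b. Over this list 6 genes rose and 2 fell, and the median of 0.90 (-0.97 in batch 2 and 4.29 in batch 3, adjusted p = 0.904) was not called. Within batches it passed with adjusted p = 0.0108 in batch 2 and 3.07e-06 in batch 3, in opposite directions. Among 12 senescence genes 6 rose, such as Igfbp5 (1.25, batches 1.51 and 0.85) and Bambi (0.91, batches 0.83 and 1.06), and 2 fell, Cdkn2b and Tnfrsf1a, which changed by -0.44 (-0.72 in batch 2 and 0.10 in batch 3). That list was not called (median 0.22 (-0.59 in batch 2 and 0.79 in batch 3, adjusted p = 0.908)).

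**Figure D3:**
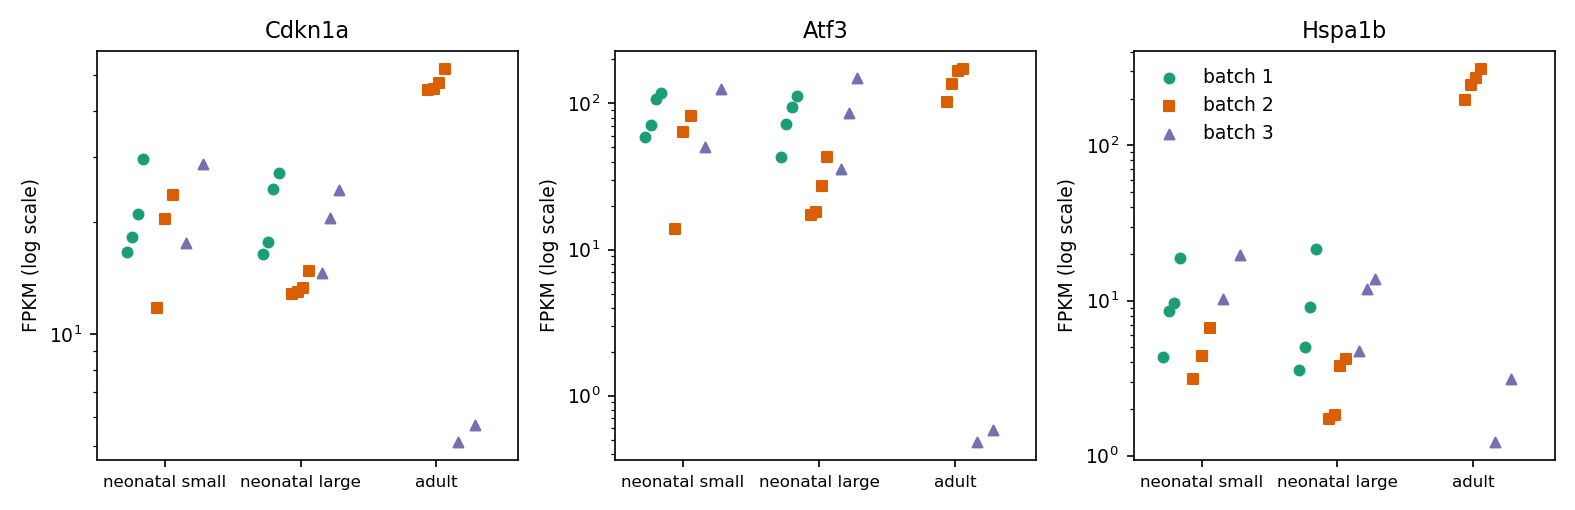
FPKM (log scale) of Cdkn1a, Atf3 and Hspa1b in each library, by group and batch. The adult libraries of batch 2 lie far above those of batch 3, with mean Hspa1b of 255 and 2.17 FPKM, and Atf3 was chosen after its values were seen.

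Transcripts of the unfolded protein response were lower in neonatal islets. Of 20 such genes 14 fell and none rose, with the largest falls in the stress-induced genes Chac1 and Trib3 (-3.33, batches -4.49 and -1.31). Both were lower in the adults of batch 3 than in those of batch 2, at 12.79 against 91.07 FPKM for Chac1 and 3.481 against 36.41 for Trib3. The median was -0.78 (-1.11 in batch 2 and -0.49 in batch 3, adjusted p = 1.1e-07), with adjusted p = 0.212 with an estimated correlation. Interferon response and MHC class I genes were mostly lower too: of 20 genes 12 fell, among them Ifit1 (-1.73, batches -2.16 and -0.91) and Rsad2 (-1.16, batches -1.55 and -0.46). The 2 that rose were Bst2 (1.01, batches 0.95 and 1.19) and Tmem173 (0.65, batches 0.61 and 0.82), while 2 rose and 13 fell when adjusted over the list alone. Their median was -0.52 (-0.62 in batch 2 and -0.32 in batch 3, adjusted p = 0.000143), with adjusted p = 0.375 with an estimated correlation. It was not called in batch 3 (adjusted p = 0.152). Of 28 antioxidant genes 15 rose, among them Gpx7 (1.70, batches 1.53 and 2.09) and Gpx8 (1.65, batches 1.70 and 1.70). The 4 that fell were Srxn1 (-1.19, batches -1.68 and -0.32), Hmox1 and, chosen after their values were seen, Txnrd1 (-0.31, batches -0.50 and 0.044) and Gclc (-0.18, batches -0.18 and -0.20). Hmox1, which encodes heme oxygenase 1, changed by -1.25 ± 0.33 (SE, adjusted p = 0.00207) over all batches, with opposite directions within them (-2.32 in batch 2 and 0.76 in batch 3). Of 39 nuclear-encoded respiratory chain genes 27 rose, led by Ndufa4 (0.98, batches 1.55 and 0.078) and Uqcrc1 (0.76, batches 0.72 and 0.86). Among the falls was Sdha (-0.22, batches -0.049 and -0.51), with 30 higher and 2 lower when adjusted over the list alone. Neither the antioxidant median (0.065 (0.062 in batch 2 and 0.19 in batch 3, adjusted p = 0.467)) nor that of the respiratory chain (0.13 (0.10 in batch 2 and 0.25 in batch 3, adjusted p = 0.0835)) was called. After median-of-ratios rescaling, 10 antioxidant genes were higher and 8 lower, and 16 and 3 respiratory chain genes.

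Markers of the other cells that islets hold also differed by age. All 15 endothelial genes rose, among them the junction genes Cdh5 (2.48, batches 2.33 and 2.76) and Cldn5 (3.04, batches 2.81 and 3.48). The endothelial median was 1.43 (1.33 in batch 2 and 1.66 in batch 3, adjusted p = 1.37e-07). Of 17 mesenchymal genes 16 rose, among them Postn (2.71, batches 2.6 and 3.09) and the collagen gene Col3a1 (2.57, batches 2.74 and 2.46). The mesenchymal median was 1.59 (1.71 in batch 2 and 1.53 in batch 3, adjusted p = 0.000155). The 15 macrophage and antigen-presenting cell genes had 5 lower, H2-Aa, H2-Eb1, Cd74 and, chosen after their values were seen, H2-Ab1 (-3.26, batches -3.28 and -3.11) and C1qa (-0.35, batches -0.42 and -0.20). The 2 higher ones were Tyrobp (0.39, 0.29 in batch 2 and 0.72 in batch 3) and Csf1r (0.27, 0.47 in batch 2 and -0.008 in batch 3), and Csf1r was at -0.073 after quantile normalization. Adjusted over the list alone, 1 was higher and 5 lower. The macrophage median was -0.30 (-0.30 in batch 2 and -0.35 in batch 3, adjusted p = 0.0032). With an estimated correlation adjusted p = 0.212 for the endothelial, 0.392 for the mesenchymal and 0.459 for the macrophage list. All 4 erythroid genes rose, the globin genes Hbb-bs (4.16, batches 3.41 and 5.66) and Hba-a2 (3.96, batches 3.31 and 5.20), whose paralogs share reads, and, chosen after their values were seen, Alas2 (2.33, batches 2.33 and 2.41) and Slc4a1 (0.80, batches 0.85 and 0.76). Their median was 3.14 before that of all genes is taken off. Of 6 duct genes 6 rose, among them Sox9 (1.75, batches 1.44 and 2.40) and Krt19 (1.70, batches 1.49 and 2.22). The duct median was 1.14 (0.99 in batch 2 and 1.33 in batch 3, adjusted p = 0.0926). Of 7 Schwann and neural genes 4 rose, among them Ngfr (1.32, batches 1.36 and 1.38) and, chosen after their values were seen, Sox10 (1.06, batches 1.03 and 1.24) and Foxd3 (0.79, batches 0.70 and 1.03). The fall was in Cdh19 (-0.30, batches -0.079 and -0.63), and the median was 0.63 (0.48 in batch 2 and 0.84 in batch 3, adjusted p = 0.4). None of 14 acinar genes passed (median 0.37 (0.74 in batch 2 and -0.47 in batch 3, adjusted p = 0.467)). Among lymphocyte genes 1 of 2 rose, Lck (0.47, batches 0.24 and 0.92), which was at -0.0015 after quantile normalization.

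Small and large neonatal islets were compared to ask whether islet size goes with a different expression program at the same age. Small islets had fewer transcripts of connective tissue, macrophage and nerve markers, lists that did not pass with an estimated correlation (adjusted p = 0.617 each). Of the 6 largest falls, 4 were in genes of the extracellular matrix (Dcn, Lum, Mfap4 and Dpt). Dcn, which encodes the matrix proteoglycan decorin, averaged 12.2 ± 13.7 FPKM in small islets (SD, n = 9) and 33.2 ± 23.7 in large ones (n = 11). Dcn changed by -1.5 ± 0.36 (SE, adjusted p = 0.009), with -1.83, -1.31 and -1.21 in batches 1, 2 and 3. Lum, which encodes lumican, averaged 5.24 ± 5.28 FPKM in small islets (SD, n = 9) and 14.4 ± 6.7 in large ones (n = 11). Lum changed by -1.44 ± 0.27 (SE, adjusted p = 0.00179), with -1.80, -1.17 and -1.24 in batches 1, 2 and 3. The other 4 of the 6 largest falls were Mfap4 (-1.37, batches -1.30, -1.25 and -1.66), Itm2a (-1.35, batches -1.78, -0.81 and -1.40), Dpt (-1.32, batches -1.62, -1.42 and -0.67) and Ces1d (-1.29, batches -1.31, -1.13 and -1.52). Rises were smaller. The 6 largest were Klhl40 (0.72, batches 1.29, 0.43 and 0.20), Rpl32l (0.57, batches 0.92, 0.34 and 0.30), Tmem198 (0.54, batches 0.57, 0.48 and 0.59), Lmtk3 (0.53, batches 1.06, 0.14 and 0.21), Lncpint (0.53, batches 0.91, 0.34 and 0.15) and the noncoding RNA Meg3 (0.52, batches 1.16, 0.12 and 0.019).

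With limma over all batches, 2363 of 13402 genes differed between small and large islets, 665 higher and 1698 lower in small ones, and 23 of the lower genes reached an absolute log2 change of 1. The number called was 566 without the batch term, 4011 with array weights and 4205 with library-name numbers as a random block. Lower genes were the majority as deposited (28.1% higher), close to even after median-of-ratios rescaling (1070 higher and 1117 lower) and the minority after quantile normalization (1475 higher and 1189 lower). These calls needed batch 1: limma called 4953 genes in batch 1 and 0 genes without it, where 1355 genes had an unadjusted p under 0.05. Within batch 2 and batch 3 it called 0 genes, with 1496 and 556 at an unadjusted p under 0.05. The 2363 genes, chosen with all batches, had a median absolute log2 change of 0.20 without batch 1 and 0.40 in it. Of the 4953 genes called in batch 1 alone, 82.7% had the same sign in batches 2 and 3. Over all 350 arrangements of those libraries within batches, 8 gave as high a percent (p = 0.0229), against 53.1% at the median of the others. The difference itself between batch 1 and the later batches passed for 472 genes, of which 164 were among the 2363. In batch 1 the small libraries were also shallower than the large ones, and both stood apart in Malat1, a nuclear noncoding RNA chosen after its values were seen. Malat1 was at 2739 to 3444 FPKM in the small and 1720 to 2595 in the large libraries of batch 1, against 509 to 1221 in the other small and 530 to 1053 in the other large ones. Between sizes Malat1 (0.23, batches 0.64, -0.029 and -0.11) passed in batch 1 alone but not over all batches (adjusted p = 0.378).

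Of the lists, 4 lay above and 9 below the other genes in small islets, and none passed with an estimated correlation. Random splits within batches called 8 lists at the median and up to 17. The lowest median among called lists was that of the 17 mesenchymal genes, of which 10 fell (0 higher and 11 lower when adjusted over the list alone). It was -0.76 (-0.80, -0.61 and -0.81 in batches 1, 2 and 3, adjusted p = 8.58e-06), with adjusted p = 0.617 with an estimated correlation. Of 15 macrophage and antigen-presenting genes 9 fell (0 higher and 13 lower when adjusted over the list alone), among them Tyrobp (-0.74, batches -0.72, -0.66 and -0.87) and H2-Aa (-0.74, batches -0.52, -0.83 and -0.98). The macrophage median was -0.43 (-0.27, -0.55 and -0.40 in batches 1, 2 and 3, adjusted p = 3.32e-05), with adjusted p = 0.617 with an estimated correlation. Of 7 Schwann and neural genes 6 fell, among them Ngfr (-0.59, batches -0.64, -0.59 and -0.51). The Schwann median was -0.35 (-0.37, -0.44 and -0.30 in batches 1, 2 and 3, adjusted p = 0.000252), with adjusted p = 0.617 with an estimated correlation. The endothelial list was not called: 1 of 15 genes fell, Emcn (-0.21, batches -0.23, -0.16 and -0.23), and the median was -0.025 (-0.04, -0.003 and -0.008 in batches 1, 2 and 3, adjusted p = 0.646). Of 6 duct genes 2 fell, Spp1 (-1.11, batches -1.09, -0.82 and -1.55) and Muc1 (-0.64, batches -0.39, -0.56 and -1.15) (median -0.47 (-0.41, -0.15 and -0.67 in batches 1, 2 and 3, adjusted p = 0.259)). Of 14 acinar genes 0 passed in limma (median -1.05 (-0.41, -0.95 and -2.24 in batches 1, 2 and 3, adjusted p = 0.214)), with a call in batch 3 alone (adjusted p = 0.000264). The duct and acinar lists were lower in the small member of all 7 pairs with equal library-name numbers. Among 4 erythroid genes 1 fell, Alas2 (-0.36, batches -0.20, -0.63 and -0.26), and neither of the 2 lymphocyte genes passed.

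**Figure D4:**
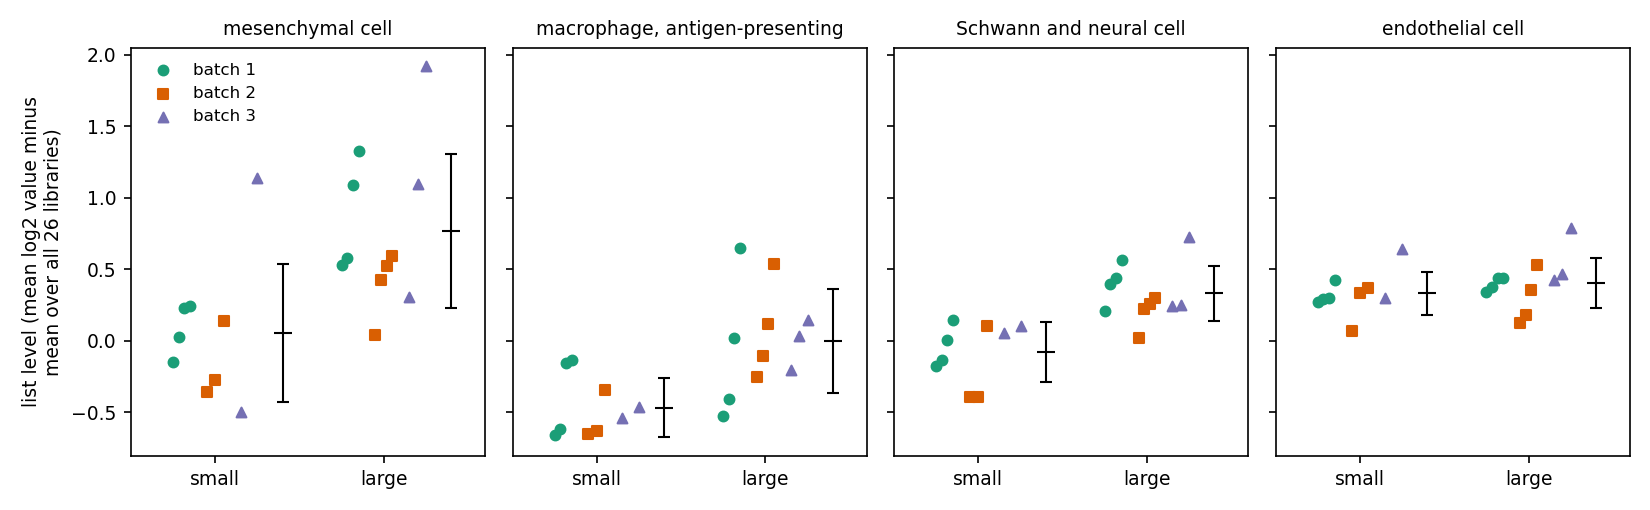
Level of the mesenchymal, macrophage, Schwann and endothelial lists (vertical axis, mean log2 value of the list minus its mean over all 26 libraries) in each neonatal library, by islet size and batch. Black marks give the mean and SD of each group. The mesenchymal list is lower in small islets, with a median log2 change of -0.79, and the endothelial list is nearly level, at -0.064.

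Another 6 lists lay slightly below the other genes in small islets, with adjusted p from 0.617 to 0.779 with an estimated correlation. Of 39 respiratory chain genes 19 fell (0 higher and 27 lower when adjusted over the list alone), among them Ndufa4 (-0.49, batches -0.71, -0.24 and -0.49) and Ndufb6 (-0.45, batches -0.69, -0.14 and -0.49). The respiratory chain median was -0.20 (-0.28, -0.062 and -0.20 in batches 1, 2 and 3, adjusted p = 7.17e-08). Of 28 antioxidant genes 11 fell (0 higher and 12 lower when adjusted over the list alone), led by Sod3 (-0.65, batches -0.74, -0.45 and -0.79) and Gpx8 (-0.64, batches -0.79, -0.35 and -0.80). The antioxidant median was -0.14 (-0.26, -0.033 and -0.11 in batches 1, 2 and 3, adjusted p = 0.0039). Of 15 disallowed genes 9 fell (0 higher and 11 lower when adjusted over the list alone), led by Mgst1 (-0.83, batches -1.46, -0.18 and -0.71) and Igfbp4 (-0.69, batches -0.81, -0.57 and -0.65). The disallowed median was -0.32 (-0.45, -0.21 and -0.38 in batches 1, 2 and 3, adjusted p = 2.23e-05). Mesenchymal and macrophage markers fell too (medians -0.76 and -0.43), so the fall is not assigned to β cells. Among 28 histone genes 13 fell (0 higher and 16 lower when adjusted over the list alone), with a median of -0.37 (-0.26, -0.34 and -0.38 in batches 1, 2 and 3, adjusted p = 1.59e-05). Among 34 S phase genes 9 fell (0 higher and 11 lower when adjusted over the list alone), led by Gins1 (-0.35, batches -0.48, -0.38 and -0.10), with a median of -0.11 (-0.087, -0.15 and -0.049 in batches 1, 2 and 3, adjusted p = 0.00292). Among 25 mitosis genes 3 fell (0 higher and 7 lower when adjusted over the list alone), Ccnb1 (-0.29, batches -0.37, -0.32 and -0.12), Cdk1 (-0.29, batches -0.28, -0.32 and -0.25) and Bub1 (-0.23, batches -0.30, -0.30 and -0.012). The mitosis median was -0.11 (-0.045, -0.25 and 0.0054 in batches 1, 2 and 3, adjusted p = 0.0039). Mki67 itself had 40.5 ± 6.75 FPKM in small and 40.8 ± 6.44 in large islets (adjusted p = 0.87, 0.067, -0.23 and 0.11 in batches 1, 2 and 3).

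The 4 lists above the other genes in small islets differed little, with adjusted p from 0.617 to 0.624 with an estimated correlation. Of 23 β cell identity genes 5 rose, among them Mafa, the glucose-responsive factor gene Mlxipl (0.49, batches 0.85, 0.17 and 0.34), the potassium channel gene Abcc8 (0.41, batches 0.62, 0.16 and 0.39) and Nkx6-1 (0.33, batches 0.25, 0.25 and 0.57). The identity median was 0.11 (0.10, 0.082 and 0.18 in batches 1, 2 and 3, adjusted p = 0.0023). Mafa rose to 166 ± 39.7 FPKM in small islets from 128 ± 29.5. Mafa changed by 0.34 ± 0.11 (SE, adjusted p = 0.0378), with 0.39, 0.33 and 0.28 in batches 1, 2 and 3. Of 25 granule genes 5 rose (7 higher and 0 lower when adjusted over the list alone), Cacna1a (0.46, batches 0.88, 0.14 and 0.20), Unc13a (0.43, batches 0.85, 0.10 and 0.19), Ptprn, Rph3al (0.25, batches 0.33, 0.14 and 0.26) and Cacna1d (0.32, batches 0.57, 0.13 and 0.17). The granule median was 0.11 (0.11, 0.077 and 0.18 in batches 1, 2 and 3, adjusted p = 0.00108). Bub1, Nkx6-1, Rph3al and Cacna1d were chosen after their values were seen. Of 10 autoantigen genes 2 rose, Ptprn (0.23, batches 0.39, 0.048 and 0.24) and Ica1 (0.17, batches 0.21, 0.12 and 0.17). Their median was 0.12 (0.08, 0.10 and 0.18 in batches 1, 2 and 3, adjusted p = 0.0474). Of 20 unfolded protein response genes 1 rose (0 over the list alone), Ern1 (0.22, batches 0.33, 0.048 and 0.27). Their median was 0.18 (0.17, 0.19 and 0.15 in batches 1, 2 and 3, adjusted p = 0.00348). The autoantigen list was not called after median-of-ratios rescaling (adjusted p = 0.0686).

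No damage response list was called between small and large islets over all batches. The test pointed higher while the median lay below 0 for the checkpoint and end joining lists, and lower while it lay above 0 for the anti-apoptotic list. Of 30 checkpoint genes 3 fell, Chek2 (-0.29, batches -0.23, -0.30 and -0.38), Tipin (-0.30, batches -0.49, -0.20 and -0.14) and Nbn (-0.14, batches -0.24, -0.13 and 0.023). The 1 that rose was Rnf8 (0.22, batches 0.36, 0.14 and 0.10), and the median was -0.012 (0.012, -0.069 and 0.048 in batches 1, 2 and 3, adjusted p = 0.967). Homologous recombination had 2 of 32 genes lower, Fancl (-0.21, batches -0.37, -0.077 and -0.15) and Rad51b (-0.22, batches -0.20, -0.12 and -0.40). Its median was -0.031 (0.064, -0.11 and 0.001 in batches 1, 2 and 3, adjusted p = 0.624), and 0.028 after quantile normalization. End joining had 1 of 13 genes higher, Polm (0.22, batches 0.48, 0.0018 and 0.12), and a median of -0.013 (0.089, 0.034 and -0.0057 in batches 1, 2 and 3, adjusted p = 0.294). Base excision repair had 1 of 22 genes lower, Mpg (-0.25, batches -0.32, -0.25 and -0.14), and a median of 0.025 (0.12, -0.015 and -0.026 in batches 1, 2 and 3, adjusted p = 0.567). Nucleotide excision repair had 1 of 23 genes higher, Ercc2 (0.18, batches 0.35, 0.072 and 0.058), and 3 lower, Rpa3 (-0.50, batches -0.62, -0.23 and -0.71), Cetn2 (-0.28, batches -0.54, -0.0093 and -0.24) and Gtf2h5 (-0.24, batches -0.37, -0.015 and -0.33). Its median was 0.026 (0.035, 0.012 and 0.018 in batches 1, 2 and 3, adjusted p = 0.763), against -0.059 (-0.019, -0.07 and -0.049 in batches 1, 2 and 3, adjusted p = 0.543) for mismatch repair with 0 of 8 called by limma. For p53 targets it was 0.063 (0.062, 0.065 and 0.038 in batches 1, 2 and 3, adjusted p = 0.517), with 1 of 26 lower, Ccng1 (-0.27, batches -0.48, -0.17 and -0.046). For senescence it was -0.13 (-0.21, 0.057 and 0.036 in batches 1, 2 and 3, adjusted p = 0.76), with 0 of 12 called by limma. Pro-apoptotic genes had a median of -0.10 (-0.0012, -0.029 and -0.10 in batches 1, 2 and 3, adjusted p = 0.442), with 0 of 17 called by limma. Anti-apoptotic genes had 0.018 (0.014, 0.026 and 0.029 in batches 1, 2 and 3, adjusted p = 0.763), with 1 of 8 lower, Bcl2 (-0.23, batches -0.30, -0.25 and -0.10). Cdkn1a had 20.9 ± 5.77 FPKM in small and 18.1 ± 5.22 in large islets (adjusted p = 0.761, -0.0053, 0.39 and 0.20 in batches 1, 2 and 3). For the immediate early list the median was 0.32 (-0.011, 0.60 and 0.38 in batches 1, 2 and 3, adjusted p = 0.173) with 0 of 13 genes called, and it passed within batch 2 (adjusted p = 1.15e-08) and batch 3 (adjusted p = 0.00348). The 15 G1 regulators had a median of -0.066 (-0.081, -0.045 and -0.0046 in batches 1, 2 and 3, adjusted p = 0.185), with 2 lower, Cdk6 (-0.25, batches -0.30, -0.15 and -0.32) and Cdk4 (-0.18, batches -0.25, -0.072 and -0.21). The 20 interferon and MHC class I genes had -0.082 (-0.06, -0.08 and -0.20 in batches 1, 2 and 3, adjusted p = 0.458), with 3 lower, B2m (-0.52, batches -0.76, -0.28 and -0.46), Tmem173 (-0.44, batches -0.51, -0.35 and -0.46) and Oasl2 (-0.37, batches -0.36, -0.40 and -0.36). For the 15 fetal genes it was -0.081 (-0.16, -0.017 and 0.011 in batches 1, 2 and 3, adjusted p = 0.707), with 4 lower, H19 (-0.77, batches -0.82, -0.87 and -0.53), Igf2 (-0.59, batches -0.71, -0.57 and -0.41), Mest (-0.52, batches -0.64, -0.46 and -0.39) and Npy (-0.54, batches -0.58, -0.61 and -0.40). Nbn, Gtf2h5, Oasl2, Mest and Npy were chosen after their values were seen.

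The hormone make-up of small and large islets differed in glucagon. Gcg made up 9.88% ± 3.3 (SD, n = 9) of hormone FPKM in small and 12.8% ± 2.59 (n = 11) in large islets. The difference of -2.88 points passed in an exact permutation test within batches, on both sides (p = 0.0147 over 24500 arrangements, adjusted p = 0.0294 over 4 tests). The difference was -4.23 points in batch 1 (exact p = 0.0857), -1.32 in batch 2 (exact p = 0.371) and -1.66 in batch 3 (exact p = 0.8), so no batch passed alone. Small and large libraries of 1 batch with equal numbers in their names, taken as pairs after the data were seen, had a lower share in the small member in all 7 pairs. The mean paired difference was -3.09 points (-4.85 to -0.222, exact sign-flip p = 0.0156 over 128 arrangements). Its limma change was -0.41 ± 0.18 (SE, adjusted p = 0.1), with -0.85, -0.094 and -0.14 in batches 1, 2 and 3. Of the 10 α cell genes 1 fell, Pou3f4 (-0.31, batches -0.64, -0.13 and -0.032) (median -0.15 (-0.22, -0.041 and 0.035 in batches 1, 2 and 3, adjusted p = 0.45)). The median of the 8 δ, PP and ε cell genes was 0.22 (0.084, 0.12 and 0.39 in batches 1, 2 and 3, adjusted p = 0.185). Ins1 (-0.019 ± 0.10 (SE, adjusted p = 0.909)) and Ins2 (0.018 ± 0.10 (SE, adjusted p = 0.921)) did not pass. Insulin made up 25.2% ± 1.79 of all FPKM in small and 24.3% ± 2.15 in large islets (exact permutation p = 0.362). The changes of Sst (0.20 ± 0.11 (SE, adjusted p = 0.193)) and Ppy (0.37 ± 0.18 (SE, adjusted p = 0.142)) did not pass.

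Each neonatal size was also set against the adult islets. Small islets differed in 8447 genes, 5779 higher and 2668 lower, and large islets in 9000 genes, 6287 higher and 2713 lower. Of these, 7457 genes changed in the same direction in both and 1 in opposite directions. After median-of-ratios rescaling the higher and lower genes numbered 4238 and 4325 for small islets, and 4396 and 4662 for large ones. Mki67 rose by 3.63 on the log2 scale in small and by 3.66 in large islets. The mesenchymal gene Col3a1 was at 71.3 ± 37.9 FPKM in small and 133 ± 60.8 in large islets, against 13.1 ± 5.58 in adult ones.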

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

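Tests chosen only after the result was seen were those of sex, immune cells and handling for the early response genes, those of every non-endocrine cell type, of batch 1 alone and of ducts for the connective tissue markers, all arrangements within batches, and exchanges within pairs, while the tests of library batch, of exocrine tissue and of random splits were planned.

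Among the neonatal small and adult libraries, a single value lay far from the others of its group. Ppy was at 7210 FPKM in neonatal small replicate 6, against 1300 to 3530 FPKM in the other 8 small libraries, a gap of 0.623 of the whole range. Chance flags about 1 in 20 groups, and this was 1 of 38 combinations of a value and a group. No explanation of it was tested.

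The difference between neonatal and adult islets differed between batches 2 and 3 for 6023 of 13402 genes, with 2555 changes higher and 3468 lower in batch 3. It rested on 2 adults in batch 3, and leaving out replicate 6 left 4472 genes and replicate 5 left 4776. Leaving out 1 of the 4 adults of batch 2 left 5510 to 5742. Of 100 splits of libraries between batches 2 and 3, within groups, 1, the real one, gave as many genes (highest other 4096). The other splits also mix any shift between batches that both ages share, which can widen their spread. With 2 adults in batch 3, they cannot exclude chance among the adults. The adults of batch 3 were also shallower than those of batch 2. They lacked Y-linked Ddx3y, which adult replicates 1 to 3 had, so a part from sex stays open.

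The clearest part of this difference was that early response and heat shock transcripts were higher in the adults of batch 2 than in those of batch 3. All 13 genes of the list passed, with a median for neonatal minus adult, that of all genes not taken off, of -0.81 in batch 2 and 4.40 in batch 3. Mean FPKM in the adults of batches 2 and 3 were 517 and 36.6 for Fos and 255 and 2.17 for Hspa1b. Neonates of batch 3 had a mean of 1320 FPKM of Fos and 12.1 of Hspa1b.

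A shift of all libraries by preparation or sequencing batch is argued against, since the neonatal libraries of batch 2 lay below those of batch 3 by a median of -0.69 over the same list. The adults of batch 2 held libraries both with and without Y-linked transcripts, and their lowest list level was 3.93 above the highest in batch 3, which argues against sex. Immune cells in the adult islets of batch 2 are argued against by a median of -0.062 over the macrophage list between the adults of batches 2 and 3. Handling of the adult islets before lysis may account for the median adult difference of 4.22 as may other differences between the adult mice, and they cannot be told apart, because the adults of each batch stand for 1 batch alone. The comparison of Cdkn1a, Atf3, heat shock and unfolded protein response genes between ages is open to the same limit.

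Connective tissue, macrophage and nerve markers were lower in small than in large neonatal islets. The medians here are those before that of all genes is taken off. A lower share of every non-endocrine cell type is argued against, since the mesenchymal median lay below the endothelial one in each batch, by -0.61 in the batch nearest 0, and by -0.732 over all neonatal libraries (exact permutation p = 0.00261). Mesenchymal markers were lower in the small member of 6 of 7 library-name pairs. Acinar and duct markers were lower in all 7 (mean -1.45 and -0.459), as attached exocrine tissue would give. As the whole cause it is argued against by a median of -0.81 with the acinar level of each library as a covariate (exact permutation p = 0.00535), against -0.794 without, while the acinar median went from -1.09 to 0.0214. Macrophage genes went from -0.466 to -0.473 and Schwann genes from -0.393 to -0.37. With the duct level as a further covariate the mesenchymal median was -0.488 (exact permutation p = 0.0462), so a part that goes with ducts stays open. The mesenchymal list did not pass with an estimated correlation (adjusted p = 0.617). Batch 1 alone as the cause stays open. The mesenchymal median was -0.71 without it, with a call by camera at the preset correlation (adjusted p = 2.32e-07), which meets the bound set for excluding it. That correlation understates how genes of 1 list move together: 31 of 350 arrangements of those libraries moved the median as far (exact permutation p = 0.0886), and limma called 0 of the 17 genes there. A larger share of connective tissue around or in large islets may also be a candidate, and islet size, dissection and hand-picking cannot be separated.

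Random splits of the libraries within batches, 100 for each comparison with the real one included, exclude chance for the numbers of called genes. Between neonatal and adult islets, 1 split, the real one, gave as many as 9096 genes, and the highest other gave 7059. That split left all 4 adults of batch 2 and 1 of the 2 of batch 3 in place. Between small and large islets the real split gave 2363 genes and the highest other 53. For small and for large islets against adult ones the real splits gave 8447 and 9000 genes and the highest others 5673 and 6699. For the numbers of called lists chance cannot be excluded: 37 of 100 splits called at least the real 15 lists between neonatal and adult islets, with 20 as the highest other, and 21 of 100 at least the real 13 between small and large, with 17 as the highest other. The splits do not use the library-name pairs. In the 14 paired libraries 24 of 64 exchanges within pairs called at least the real 12 lists, with 17 as the highest other, while for genes the real one called 3129 and all others 0. In all 7 pairs 9 of the 32 lists were lower in the small member, the disallowed, S phase, G1 regulator, acinar and duct lists among them, and 1, the granule list, was higher. Genes of 1 list move together across libraries, which the preset correlation understates. Taken list by list, fewer than 5 of the 100 splits moved the median as far as the real split for 22 of 32 lists between ages and for 14 of 32 between sizes, the mesenchymal list among them (2 splits, highest other 0.83).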

How the results depend on the processing

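Tests chosen only after the result was seen were voom on recovered counts, the fits without the adults of batch 2 or of batch 3 and without neonatal large replicate 14, batch 1 alone, pairs of libraries for the hormone shares, and, for lists, single batches, quantile normalization and each adult left out. The share of insulin among FPKM without mitochondrially encoded genes was not run, because no such gene was among the genes.

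Between neonatal and adult islets the number of called genes stayed within 1.5 times 9096 under every alternative run except a minimum absolute log2 change of 1, and ranged from 6608 under the FPKM minimum of 5, where fewer genes were tested, to 10398 with array weights. With that minimum change the numbers were 1571 between neonatal and adult islets, 23 between small and large, 1429 for small and 1790 for large islets against adult ones, which is how the alternative is built. Higher and lower genes past that change numbered 441 and 96 between neonatal and adult islets with the pseudocount of 5 and 2213 and 400 with voom. Between small and large, the lower ones numbered 120 with the pseudocount of 0.1, 139 with voom and 5 with the pseudocount of 5. In batch 3 alone, with 2 small and 2 adult libraries, 5497 genes differed between them. Leaving out each adult in turn gave 8800 to 8908 genes for neonatal, 8193 to 8323 for small and 8715 to 8929 for large islets against adult ones, and 4472 to 5742 for the difference between batches. It gave 15 to 19 called lists, an insulin share difference of -7.23 to -5.75 points (exact permutation p = 0.000794 to 0.00253), and an α cell hormone share difference of -2.09 to 0.198 points (exact permutation p = 0.161 to 0.914).

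Between small and large islets the count of 2363 genes depended on several settings. It was 1569 with the FPKM minimum of 5, 566 without the batch term, 4011 with array weights and 4205 with the library-name number as a random block, and the cause was not tested. Batch 1 alone gave 4953 genes with limma, against 0 in batch 2, 0 in batch 3 and 0 without batch 1, with 1496, 556 and 1355 genes at an unadjusted p under 0.05. Simulated changes of 0.5 or 1 were found in the libraries without batch 1, but changes as small as the median there (0.20) were not simulated, so whether fewer libraries explain the 0 is open. The α cell hormone share difference was -4.23 points in batch 1 (exact permutation p = 0.0857), -1.32 in batch 2 (0.371) and -1.66 in batch 3 (0.8), where fewer libraries were compared, and -3.09 in 7 pairs (0.0156).

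With the number in the sample titles as a replicate block and no batch term, small islets differed from adult ones in 8177 genes. With the library-name number within batch as a replicate block, small and large islets differed in 3134 genes. Equal library-name numbers went with r from -0.16 to 0.63 in 7 pairs, 6 of them best with their own number, and equal title numbers with r from -0.21 to 0.33 in 6 pairs, 1 best, so only the first may pair libraries.

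With an estimated correlation 0 of the 15 lists called between neonatal and adult islets passed and 0 of the 13 between small and large, because camera then allows for genes that move together. fry, which does not compare a list with other genes, called 28 between neonatal and adult islets, 23 of them higher, and 9 between small and large, all lower, so none of the 4 lists above the other genes in small islets. Between small and large, batch 1 alone called 5 lists, batch 2 15, batch 3 14 and the libraries without batch 1 16, against 13 over all. For end joining, senescence and anti-apoptotic genes (medians relative to all genes -0.0484, 0.224 and -0.0719) fry called a rise against 0 where camera, against the other genes, pointed lower. The immediate early list turned to -0.969 in batch 2 alone and -0.997 without the adults of batch 3, and the mitosis list between small and large islets to 0.00544 in batch 3 alone.

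Genes whose log2 change took the opposite sign did so mostly where 1 set of adults was left out. In batch 3 alone and without the adults of batch 2, in that order, changes were 0.295 and 0.307 for Birc3, 1.78 and 1.77 for Cdkn1a, -0.0422 and -0.0458 for Csf1r, 0.708 and 0.714 for Hmox1, 1.89 and 1.88 for Hspa1a, 2.05 and 2.03 for Hspa1b, 0.11 and 0.106 for Mdm2, 0.0796 and 0.11 for Plk3, 0.0856 and 0.0842 for Tnfrsf1a and 0.0586 and 0.0414 for Txnrd1. In batch 2 alone, with array weights and without the adults of batch 3, they were -2.1, -1.93 and -2.13 for Atf3, 0.388, 0.312 and 0.388 for Atm and -0.0377, -0.0317 and -0.0519 for Mcl1. Array weights gave the adults of batch 3 the lowest weights, 0.112 and 0.105. Median-of-ratios rescaling and voom with such factors gave -0.0339 and -0.0346 for Ica1, -0.00557 and -0.0053 for Nkx6-1 and -0.00363 and -0.0038 for Poll. Quantile normalization gave -0.0728 for Csf1r, -0.00148 for Lck and -0.0861 for Poll. Between ages both scalings lowered the median change of all genes, from 0.16 to -0.018 and -0.061. Dclre1c was at 0.0335 without the batch term, and Nbn between small and large islets at 0.0228 in batch 3 alone, and the cause was not tested. Of 4629 settings of 196 gene results, 3983 kept direction and side of the threshold, 590 fell short of it, 16 newly passed and 40 reversed, and of 928 settings of 64 list results 812, 59, 51 and 6 did. Totals of 15.5 M to 32.0 M fragments limit genes near 1 FPKM most, and lists and genes that rest on the 2 adults of batch 3 are limited by that number.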

Other observations

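Tests chosen only after the result was seen were both tests of scaling, while the test of the relation with mitosis was planned.

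Homologous recombination and Fanconi genes passed as higher in neonatal islets at the preset correlation (adjusted p = 4.62e-06) but not at an estimated one (0.212), and no other repair list was called. Before that of all genes is taken off, their median was 0.84 as deposited and at least 0.40 under median-of-ratios and quantile scaling, so scaling accounts for part of it at most. For nucleotide excision repair this median was 0.22 as deposited and at most 0.045 under them. Its members went both ways there, 8 higher and 3 lower after median-of-ratios rescaling and 8 and 7 after quantile normalization, so scaling as the cause of its rises stays open. Whether cells of neonatal islets repair DNA differently was not tested.

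Whether repair transcripts follow the share of dividing cells was tested in the 20 neonatal libraries, with levels centred within batches. The homologous recombination and Fanconi list followed the mitosis list, with Pearson r = 0.863 (permutation p = 0.00036, adjusted p = 0.00162 over 6 relations) and Spearman rho = 0.809 (permutation p = 8e-05). It was r = 0.659 without the 2 libraries farthest from the median, 0.566 in the 8 libraries of batch 1 and 0.968 in the 7 of batch 2, and batch 3 held too few (5). For checkpoint genes r = 0.802 (adjusted permutation p = 0.00162) and for mismatch repair r = 0.665 (0.0248), but there Spearman rho = 0.463 did not pass (permutation p = 0.0511) and r was 0.466 without the 2 farthest libraries. Base excision repair (r = 0.445, adjusted permutation p = 0.0986), nucleotide excision repair (0.317, 0.103) and end joining (-0.129, 0.545) did not pass. Permutation ignored pairs by library-name number, so its p may be too small. Dividing cells as a source of homologous recombination transcripts remain a hypothesis. Some of these repair genes act in S phase, so part of the relation follows from list choice.

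Other values were read library by library. Xist was at 0.0183 and 0.0165 FPKM in adult replicates 1 and 2, where Ddx3y was at 29 and 27.2. Adult replicate 3 had 35.5 FPKM of Xist and 1.84 of Ddx3y, and adult replicates 4, 5 and 6 had Xist of 84.6, 120 and 122 and Ddx3y at 0. All neonatal libraries had both, with Ddx3y from 2.09 to 11.04 FPKM. Neonatal large replicate 14 had 404 FPKM of the acinar gene Prss2 and a median correlation of 0.945 with its own group, and adult replicate 1 had 445. The array weight of neonatal large replicate 14 was 0.167, the lowest among the neonatal libraries.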
